A study of Mus musculus with 2 samples.

How the data were processed

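Mouse epidermal cells in 2 single-cell RNA libraries were compared, 1 labelled Bap1 wild type and 1 labelled Bap1 knockout. Per the labels' protocols, neonates of 1 genotype were pooled for each library, cultured for 7 days and dissociated, and about 6000 viable cells were loaded on a 10x Genomics Chromium 3′ kit with molecular identifiers. The submitters' processing notes name the mouse build mm10, Cell Ranger 2.1 and Seurat 2.0, without the role of each. The authors deposited a table of counts per library, genes by cells, and its whole numbers were read as UMI counts. Which intronic or antisense reads were counted, how barcodes were called as cells and whether doublets were removed are not given in the sources used here.

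The deposited tables held 1926 and 1760 cells with 77579465 and 64954113 counts. Of 36528 NCBI gene identifiers, 31049 matched a symbol in the RefSeq table of assembly GRCm38.p6, which also gave the coordinates. The other 5479 stayed in the totals with 2.67% of all counts. Cells were kept with at least 500 detected genes and at most 10% of UMIs from mitochondrially encoded genes, which removed 13 and 16 cells. Scrublet, run in each library with an assumed doublet rate of 0.02, marked 1 (0.0519%) and 7 (0.398%) of the deposited cells as doublets. After both filters 1912 and 1738 cells were left. Deep cells with both pigment and keratin RNA stayed in place.

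Cells of both libraries were clustered together without batch integration, with totals scaled to 10000, a log transform, 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5. Clusters were named only from markers fixed before the data were examined. A melanocyte-like, Schwann-like or myeloid-like name needed at least 3 markers at 5-fold or more over the mean of the other clusters. It also needed more of them than any other set gave. Clusters with no such set, or led by keratinocyte markers, were joined as keratin-rich, and a cluster led by another set stayed unnamed. Cell types therefore rest on rebuilt names. Counts were summed per class and library and divided by the class total and scaled to CPM. Genes were ranked and named by the rule only in a class with at least 100 cells in both libraries, which only the clusters 0 to 5 together reached, with 74041081 and 61494925 UMIs. Single genes of smaller classes are given as values chosen after they were seen, apart from those fixed by name. Sums have exact Poisson intervals, ratios conditional exact intervals and shares Clopper-Pearson intervals, all at 95%. With 1 sample per group no test was possible, and no p-value or standard error is given.

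The named genes follow a rule fixed before the data were examined. They are the 12 genes with the highest and the 12 with the lowest ratio among those with at least 100 UMIs and a 2-fold ratio, and 8 genes fixed by name. The ranking left out 57 genes at 10 times the level in another class of at least 50 cells (free RNA) and 108 by name (sex chromosome genes, haemoglobins and gene models with only a number). A ratio against 0 UMIs used a floor of 3. A gene with 0 UMIs in both libraries of a cluster therefore took its direction there from the totals alone. Gene lists, 34 in number and fixed at the same time, were summarised by the median log2 ratio of members with at least 20 UMIs, and a member counted as higher or lower at 1.5-fold. Percentiles came from 10000 random lists matched on size and mean expression in 25 bins, and intervals of medians from 2000 bootstrap draws of genes. Detection was compared after thinning each cell to 2000 UMIs. Which lists and genes are described at length was chosen after their values were seen.

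The ratios and the lists were tested on Poisson counts drawn from the sums over all cells kept of the library labelled wild type. Such draws hold no variation between cells, clusters or libraries. They check the code and give no rate of false calls for real libraries. Of 50 genes planted at each of 4-fold and 3-fold higher and lower, 50 were found each time at the 2-fold limit, and 0 of 13657 unchanged genes passed it. A G2 and M phase list planted at a log2 ratio of −1 was found at −1.01 with percentile 0, and 1 of 33 other lists fell outside the middle 95%. Alternatives fixed beforehand were other cell filters, doublets kept, Leiden resolutions 0.3 and 1, class assignment by mean marker level, ratios centred on their median, equal weight for each cell, thinning, and other UMI minimums. Added after seeing the data were a common UMI minimum of 10065, leaving out the top cell of each library, equal weight for each cluster, leaving out cluster 3 or cluster 4, and thinning to 8000. The work used Python 3.11.15, scanpy 1.11.5 (with its Scrublet), anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.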

Results

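The series compared mouse epidermal cells with and without deletion of Bap1, the gene of a nuclear deubiquitinase that removes ubiquitin from histone H2A. Epidermal cells of C57BL/6 mice at postnatal day 1 were pooled by genotype. The first pool came from 11 neonates with the tamoxifen-inducible recombinase CreERT2 at the Rosa26 locus, the other from 9 neonates with CreERT2 and floxed Bap1. Both cultures received 4-hydroxytamoxifen, which activates the recombinase, at 100 nM for 4 days and were collected after 3 further days in a medium with a growth supplement for melanocytes. Each pool gave 1 droplet single-cell RNA library. The library labelled wild type held 77579465 unique molecular identifiers (UMIs) in 1926 cells, with a median of 37223 and a minimum of 10065 UMIs per cell. The library labelled knockout held 64954113 UMIs in 1760 cells, with a median of 33585 and a minimum of 8776. With 1 library per genotype there was no spread between replicates and no test was made. Every 95% interval covers counting error only, except those of gene list medians, which cover the spread between the genes of a list. Every difference is one between these 2 libraries.

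Bap1 RNA was higher in the library labelled knockout. The gene (identifier 104416) lies on chromosome 14 at 31251352 to 31259930 in the GRCm38 assembly and overlaps no other annotated gene. Over all cells kept it had 1088 UMIs in the library labelled wild type and 1279 in the library labelled knockout. These were 14.1 and 19.8 CPM (UMI counts scaled to the same total in each library and class), a log2 ratio of 0.50 (0.38 to 0.61). In the keratin-rich clusters 0 to 5 the values were 14.0 and 19.6 CPM, with the higher value in the library labelled knockout in 6 of 6 clusters. Melanocyte-like cells had 17.0 and 27.1 CPM from 9 and 37 UMIs, Schwann-like cells 18.2 and 28.1 from 15 and 12, and myeloid-like cells 10.2 and 14.0 from 8 and 5. The value goes against the label, so the libraries are named by their labels and every direction given here rests on those labels. The kit counts tags at the 3′ end of transcripts and the deleted exons are not given in the sources used here. A tag outside the deleted part checks nothing.

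Pigment cells took a larger share of the library labelled knockout. Melanocyte-like cells expressed Dct, Pmel and Mlana, genes of melanin synthesis and of the melanosome. They were 28 of 1912 cells kept in the library labelled wild type (1.46%, exact Clopper-Pearson interval 0.975 to 2.11%) and 72 of 1738 in the library labelled knockout (4.14%, 3.26 to 5.19%). Schwann-like cells, with the glial gene Fabp7 and the nerve growth factor receptor gene Ngfr, were 59 (3.09%, 2.36 to 3.96%) and 35 (2.01%, 1.41 to 2.79%). Myeloid-like cells, with Lyz2 (lysozyme) and the immune receptor adaptors Fcer1g and Tyrobp, were 36 (1.88%, 1.32 to 2.60%) and 20 (1.15%, 0.704 to 1.77%). The keratin-rich clusters 0 to 5 held 1747 (91.4%) and 1579 (90.9%) of the cells.

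The clusters 0 to 5 were compared by number and carry no cell type name. Cluster 0 had 5 markers of suprabasal keratinocytes at 5-fold or more over the other clusters, and clusters 1 to 5 had no set with 3. Cluster 1 led with Krt18, a keratin of simple epithelia that also marks Merkel cells, and cluster 2 with Acta2, the smooth muscle actin. Cluster 6, with Crabp1, Twist2 and other markers of fibroblasts and of skeletal muscle, also stayed without a name and held 2.20% and 1.84% of the cells. Of the muscle marker Myog, all 211 UMIs in cluster 6 lay in 1 cell of the library labelled wild type. Of the 72 melanocyte-like cells in the library labelled knockout, 28 had fewer UMIs than the lowest deposited cell of the other library. With 10065 UMIs as the minimum in both libraries, the same cells were 28 of 1912 (1.46%) and 44 of 1672 (2.63%, 1.92 to 3.52%). When the cells above that minimum were clustered again, the shares were 1.05% (20 cells) and 1.67% (28 cells), a ratio of 1.60 whose interval, 0.870 to 3.00, includes 1. Schwann-like cells were then 59 (3.09%) and 24 (1.44%), a ratio of 0.465 (0.277 to 0.759). The common minimum removed cells of the library labelled knockout only.

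**Figure D1:**
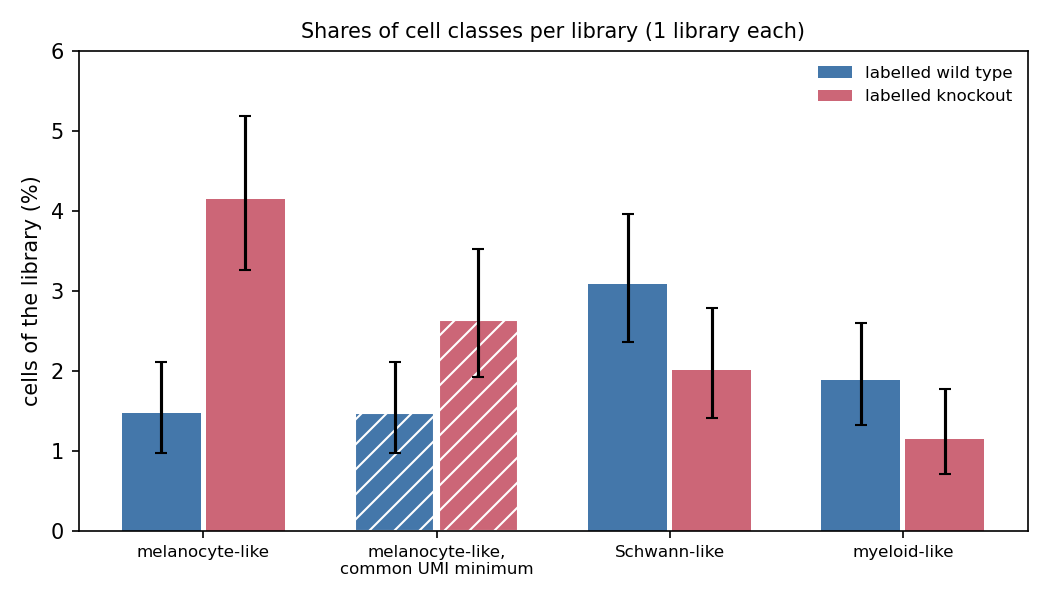
Share of the kept cells of each library (%, vertical axis) in the melanocyte-like, Schwann-like and myeloid-like classes, with exact binomial 95% intervals that cover counting error only; hatched bars count melanocyte-like cells with at least 10065 UMIs. The melanocyte-like share is 1.46% in the library labelled wild type and 4.14% in the library labelled knockout, and 2.63% in the latter at the common minimum.

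The melanocyte-like cluster was mixed. A level of 20000 CPM from Dct, Pmel, Mlana and Tyrp1 together, chosen after the values were seen, left 20 cells (1.05%, 0.640 to 1.61%) in the library labelled wild type and 53 (3.05%, 2.29 to 3.97%) in the library labelled knockout. The 8 and 19 cells under the level had median depths of 41240 and 40176 UMIs and a median Krt14, a basal keratin, of 2897 and 1703 CPM. In the cells over the level Krt14 had medians of 452 and 285 CPM at median depths of 10993 and 10294 UMIs. In each library 4 cells lay within 1.5-fold of the level.

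In clusters 0 to 5, Esr1, Hsd11b2 and Mdk were among the genes with the highest ratios, and Gsdmd and Tnfsf15 among those with the lowest. Esr1, the estrogen receptor alpha gene, had 98 UMIs in the library labelled wild type and 1352 in the library labelled knockout. That is 1.32 and 22.0 CPM, a 16.6-fold higher level (log2 4.05, 3.76 to 4.36). Hsd11b2, which inactivates glucocorticoids, was 14.9-fold higher, from 0.959 to 14.3 CPM (log2 3.89, 3.54 to 4.26). Mdk, which encodes the heparin-binding growth factor midkine, was 7.67-fold higher, from 5.19 to 39.8 CPM (log2 2.94, 2.78 to 3.10). Gsdmd, the pore-forming effector of pyroptosis, was 10.8-fold lower, from 3.17 to 0.293 CPM (log2 −3.44, −4.22 to −2.75), and Tnfsf15, a cytokine of the tumour necrosis factor family, 12.6-fold lower, from 6.56 to 0.520 (log2 −3.66, −4.22 to −3.14). In GRCm38, Esr1 lies on chromosome 10 at 4611989 to 5005633, Hsd11b2 on chromosome 8 at 105518746 to 105523988, Mdk on chromosome 2 at 91929805 to 91932297, Gsdmd on chromosome 15 at 75862144 to 75867408 and Tnfsf15 on chromosome 4 at 63724600 to 63745059.

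Of 13537 genes with at least 100 UMIs in clusters 0 to 5, 255 were at least 2-fold higher and 900 at least 2-fold lower in the library labelled knockout. In each of the 6 clusters 123 of the higher and 593 of the lower genes had the same direction. Where a gene had 0 UMIs in both libraries of a cluster, the totals alone set its direction there. All these counts are by size, with no replicate check. Different clusters held the most cells in each library, cluster 1 with 650 of 1747 (37.2%) in the library labelled wild type and cluster 5 with 638 of 1579 (40.4%) in the library labelled knockout. Cluster 5 led with Nupr1 and Gdf15, genes induced by cell stress, and with Gas6, a ligand of the Axl receptor. As a cluster mostly of 1 library, it need not be a cell type.

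Among the other genes with the highest ratios, Cnih2, an auxiliary subunit of AMPA glutamate receptors, was 25.4-fold higher. F2rl2, a protease-activated receptor, was 14.2-fold higher, Gfra2, the neurturin receptor, 10.8-fold, the neuronal pentraxin gene Nptx2 10.0-fold and the inhibitory lectin receptor gene Clec12a 9.89-fold. Angptl7, a secreted angiopoietin-like protein, had 2 and 210 UMIs (log2 6.98, 5.11 to 10.04). Obp2a, which encodes an odorant-binding protein, had 2 and 275 UMIs (log2 7.37, 5.50 to 10.42), spread over 236 cells of the library labelled knockout. In that library 1 cell of cluster 6 held 2587, and cluster 6 had 2964 CPM against 4.47 in clusters 0 to 5. The rule for free RNA did not cover cluster 6, with 42 and 32 cells. Whether the Obp2a UMIs in clusters 0 to 5 were free RNA from that cell was not tested. Within clusters 0 to 5, the next pair rested on 1 cell each of the library labelled knockout. Mcpt1, a mast cell protease, had 0 and 145 UMIs, at least 58.2-fold higher against a floor of 3 UMIs in the library labelled wild type, and 1 cell held 95.2% of them. Without that cell 7 UMIs remained, at least 2.81-fold higher against the same floor. With 0 UMIs in the library labelled wild type, Mcpt1 was lower in no cluster, and outside cluster 0 its directions come from the floor. Lce1m, a late cornified envelope gene, was 20.4-fold higher, and 3.83-fold without the cell that held 84.1% of its UMIs. Of these 12 higher genes, 8 had the same direction in all 6 clusters. Angptl7 and Clec12a among them had the same log2 ratio in cluster 0, 0.546. Equal UMIs, or 0 in both libraries, give that value from the cluster totals alone.

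The late cornified envelope genes Lce3a, Lce3f and Lce3d on chromosome 3 had the 3 lowest ratios. Lce3a had 1701 and 2 UMIs (log2 −9.46), Lce3f 2107 and 9 (log2 −7.60) and Lce3d 480 and 5 (log2 −6.32), between positions 92925287 and 92993426. From the same epidermal differentiation complex, Sprr2e was 25.04-fold lower, Sprr2j-ps 23.6-fold and Prr9 14.6-fold. For each of these 6 genes a single cell of the library labelled wild type held over 50% of the UMIs, up to 94.0% for Lce3a. Without the top cell of each library the log2 ratios were −6.40 for Lce3a, −5.15 for Lce3f and −5.53 for Lce3d, and the other 3 genes were 7.60-fold, 9.19-fold and 5.17-fold lower. The remaining genes were Clip3, a microtubule-binding protein (20.3-fold lower), the neuritin gene Nrn1 (13.7-fold), Hrob, a factor of DNA recombination repair (11.8-fold), and Cdc25b, a phosphatase that activates CDK1 (11.6-fold). Of the 12 lower genes, 6 had the same direction in all 6 clusters, and Hrob in 3 of 6. In cluster 4, Cdc25b, 1 of the 6, and Hrob both had a log2 ratio of −0.071. Equal UMIs, or 0 in both libraries, give that value from the totals alone, as they do the −3.94 of Hrob in cluster 5. Lce and Sprr2 genes have near-identical copies, and 1 other identifier had the same UMI sums as Lce3f. Angptl7, Cnih2, F2rl2 and Mdk overlap Mtor, Yif1a, Iqgap2 and Chrm4, and Mdk, Tnfsf15, Gfra2 and Nrn1 overlap gene models named only by a number, so these ratios are uncertain where counting could not tell the genes apart. With the 6 clusters weighted equally, the log2 ratio of Hsd11b2 was 3.08, the log2 ratio of Gfra2 1.22, the log2 ratio of Gsdmd −2.77 and the log2 ratio of Cdc25b −1.80. Without cluster 3, the log2 ratio of Tnfsf15 was −2.77 and the log2 ratio of Hrob −1.46.

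**Figure D2:**
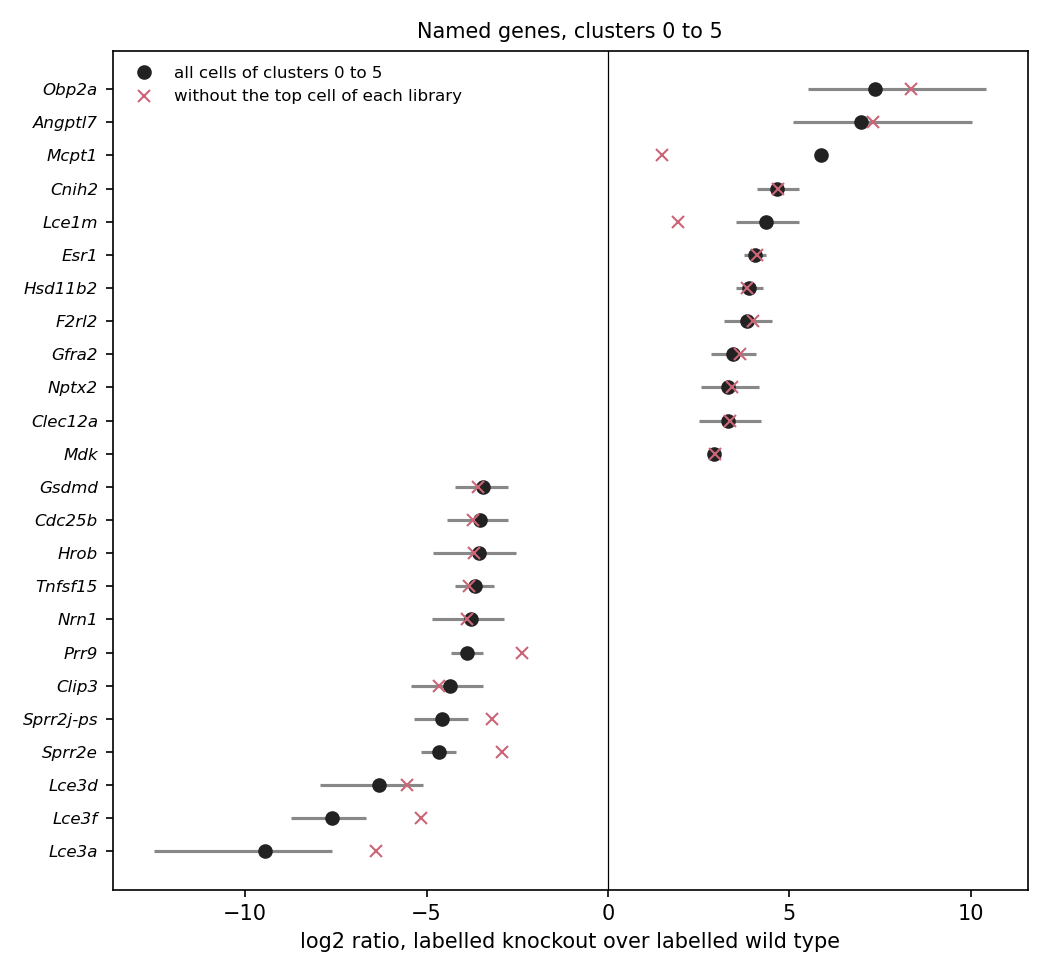
Log2 ratio of CPM in clusters 0 to 5, the library labelled knockout over the library labelled wild type (horizontal axis), for the 12 genes with the highest and the 12 with the lowest ratio; points use all cells with exact 95% intervals for counting error (Mcpt1, with 0 UMIs in the library labelled wild type, is drawn at its bound from a floor of 3 UMIs), and crosses leave out the top cell of each library. Esr1 at 4.05 and Mdk at 2.94 barely move without their top cells, while Lce3a goes from −9.46 to −6.40.

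Genes of cell survival named before the data were examined differed by less than 1.5-fold. In clusters 0 to 5 the log2 ratio was 0.39 (0.22 to 0.56) for Birc2 and −0.22 (−0.35 to −0.10) for Birc3, both inhibitors of apoptosis. It was −0.37 (−0.49 to −0.26) for the anti-apoptotic Bcl2 and 0.11 (0.05 to 0.16) for its relative Mcl1. Cdkn1a, the CDK inhibitor p21, had 2028 and 2539 CPM (0.32, 0.31 to 0.33). Slc7a11, the cystine transporter, had a log2 ratio of −0.23 (−0.43 to −0.03), and Mitf, the transcription factor of melanocytes, −0.47 (−0.74 to −0.20). The Mitf RNA of clusters 0 to 5, 4.23 and 3.06 CPM, may be free RNA from pigment cells, which was not tested. In melanocyte-like cells Mitf had 217 and 160.2 CPM (−0.44, −0.77 to −0.10) and Cdkn1a 973 and 1548 (0.67, 0.53 to 0.81). Bcl2 (−0.19, −0.75 to 0.40) and Mcl1 (0.27, −0.35 to 0.92) did not differ detectably in this mixed cluster, and Birc2 and Birc3 had 7 and 19 UMIs each. In the cells over the pigment level Mitf had 403 and 315 CPM (−0.36, −0.72 to 0.013), an interval that includes 0. Slc7a11 was highest in myeloid-like cells, with 1045 and 1231 CPM against 6.86 and 5.85 in clusters 0 to 5. The X-linked Xist had 331 and 284 CPM in clusters 0 to 5 and the Y-linked Ddx3y 15.7 and 17.7.

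Cell cycle genes were lower in clusters 0 to 5 of the library labelled knockout. Of 52 genes of G2 and M phase measured, 38 were at least 1.5-fold lower and 0 higher, with a median log2 ratio of −1.58 (bootstrap interval over genes −1.92 to −1.08). Ube2c, an enzyme that targets mitotic proteins for destruction, had 145 and 36.9 CPM, the mitotic kinase gene Cdk1 81.7 and 22.8, the topoisomerase gene Top2a 29.5 and 5.68 and Birc5, a subunit of the chromosomal passenger complex, 57.8 and 13.4. Of 42 S phase genes 20 were lower and 0 higher (median −0.56), among them Rrm2, a subunit of ribonucleotide reductase (45.7 and 13.1), and the primase gene Prim1 (10.6 and 2.68). Both medians lay below all 10000 random lists matched on size and expression (percentile 0). The G2 and M phase list had a median of 0.03 (−0.08 to 0.12) inside cluster 3, which these genes set apart from the other clusters. It was −0.67 (−1.15 to −0.20) in cluster 1, −0.50 (−1.18 to −0.21) in cluster 2 and −0.35 (−0.57 to −0.16, percentile 5.91) in cluster 5. In cluster 0, at −0.10 (−0.44 to 0.17), and cluster 4, at −0.12 (−0.55 to 0.17), the interval included 0. The list had a median of −0.025 (−0.16 to 0.12) with the 6 clusters weighted equally. The S phase median was 0.047 without cluster 3.

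After thinning each cell to 2000 UMIs, with 0 cells left out, 9.16% (7.85 to 10.6%) and 2.15% (1.496 to 2.996%) of the cells in clusters 0 to 5 had a Ube2c UMI. Without thinning the shares were 38.9% and 20.3%, at median depths of 39612 and 35581 UMIs. Thinned myeloid-like cells, with median depths of 19444 and 16120 UMIs before thinning, had Ube2c in 2 of 36 cells (5.56%, 0.680 to 18.7%) and 0 of 20, where 3 counts of the total would be a share of 15% of cells with a UMI. These few cells set no background, since they held Ube2c themselves. At 8000 UMIs it was in 10 of 36 (27.8%) and 1 of 20 (5%), against 15.5% and 5.70% in clusters 0 to 5. Whether free RNA adds to the shares of clusters 0 to 5 stays undecided.

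Lists of keratinocyte stress and wounding, of interferon response and of NF-kB signalling also had medians below those of their random lists. Of 14 stress and wound genes 8 were lower and 3 higher, with a median of −1.02 (−1.87 to −0.057) at percentile 0, but 0.13 in cluster 1. The calprotectin gene S100a8 had 149 and 40.9 CPM, the proline-rich Sprr2h 149.9 and 35.8 and the cytokine Il24 8.79 and 2.31, while Krt6b, a wound keratin, had 17.5 and 28.3 and the defensin Defb14 46.2 and 74.7. Of 22 interferon response genes 13 were lower and 0 higher (median −0.69, −0.95 to −0.28, percentile 0.05), such as the antiviral genes Bst2 (264 and 169.9), Isg15 (18.5 and 8.51) and Xaf1 (9.44 and 4.13). Of 19 NF-kB targets 5 were lower and 2 higher (median −0.33, −0.48 to 0.032, percentile 0.01), an interval that includes 0. The chemokine Cxcl5 had 504 and 154 CPM, Il1a, the interleukin 1 alpha gene, 341 and 148 and the adhesion molecule Icam1 112 and 55.7, against 113 and 188 for the monocyte chemokine Ccl2. Of 11 genes of MHC class I presentation 4 were lower and 0 higher (median −0.39, percentile 0.63). Psmb8, a subunit of the immunoproteasome, had 22.6 and 2.94 CPM, and the peptide transporter Tap2 19.9 and 10.3.

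Basal keratinocyte and hemidesmosome genes had a median of −0.37 (6 of 15 lower, 0 higher, percentile 0), with an interval of −0.88 to 0.11 that includes 0 and a median of 0.17 in cluster 0. Krt5, a basal keratin, had 1060.0 and 597 CPM, the hemidesmosomal collagen Col17a1 32.2 and 9.58 and Trp63, the transcription factor p63, 26.1 and 12.99. Cholesterol synthesis genes had a median of −0.26 (3 of 22 lower, 0 higher, percentile 0.03), but 0.079 in cluster 1 and 0.11 in cluster 2. YAP and TGF-beta targets had a median of −0.14 (−0.30 to 0.13, 0 of 14 lower, 1 higher, percentile 1.63), the higher gene being Ankrd1 at 80.4 and 159.7 CPM. Immediate early genes had a median of −0.12 (−0.58 to 0.049, 4 of 16 lower, 0 higher, percentile 2.19), slightly above 0 in clusters 1 and 3, with the transcription factors Fos at 79.4 and 32.7 and Egr1 at 33.1 and 14.1. The intervals of the YAP and immediate early medians include 0. These 10 lists lay at or below percentile 2.5 of their random lists, and none of the 34 lists lay above the middle 95% of its own. The medians of interferon, NF-kB, MHC class I and YAP genes were negative in all 6 clusters.

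**Figure D3:**
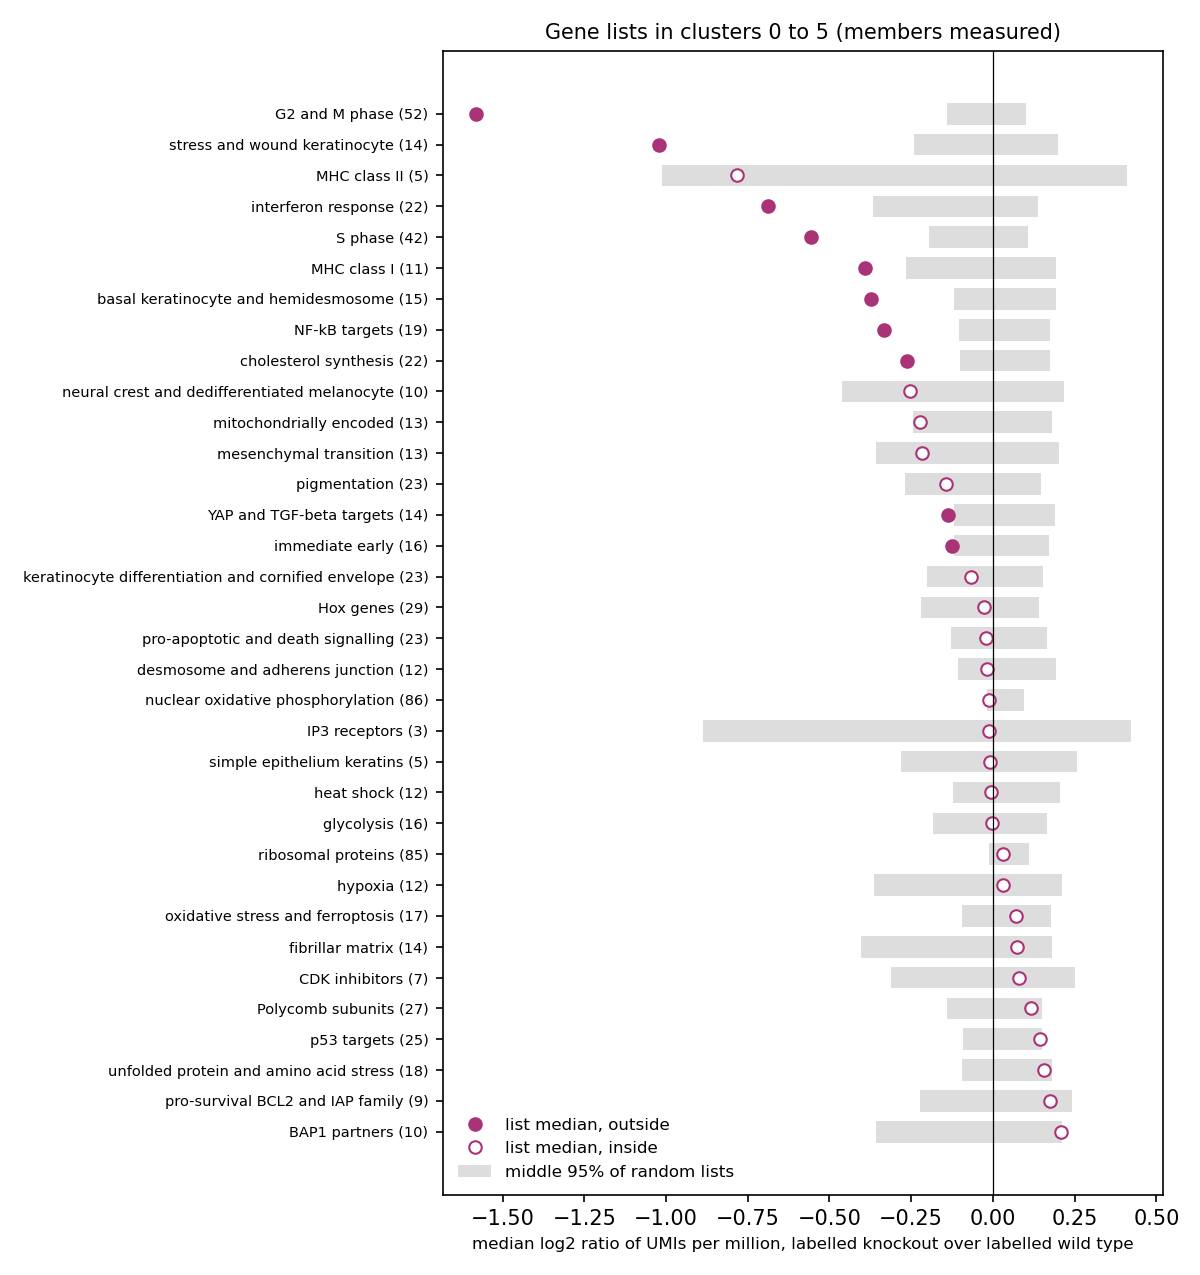
Median log2 ratio of each gene list in clusters 0 to 5, the library labelled knockout over the library labelled wild type (horizontal axis), with the number of members measured beside each list; grey bars span the middle 95% of 10000 random lists matched on size and expression. Filled points lie outside that range, all on the lower side, with G2 and M phase at −1.58 and stress and wound genes at −1.02.

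The other 24 lists had medians between those percentiles, and several held genes that went both ways. Cornified envelope genes (median −0.07, 9 of 23 lower, 2 higher, percentile 24.5) included Sprr2d at 298 and 44.1 CPM and Cnfn at 163 and 43.6, but Sprr1a at 277 and 909.7. Fibrillar matrix genes (0.08, 5 of 14 lower, 4 higher, percentile 86.9) included fibronectin Fn1 at 354 and 1038 and periostin Postn at 24.7 and 64.8, but fibulin Fbln1 at 14.0 and 3.48. Mesenchymal transition genes (−0.22, 3 of 13 lower, 3 higher, percentile 10.6) included tenascin Tnc at 303 and 750.1. The simple epithelium keratins Krt8 (313 and 510.2) and Krt18 (4519 and 7241) were the 2 higher of 5 (median −0.01, percentile 41.6). Among p53 targets (0.14, 0 of 25 lower, 3 higher, percentile 96.6) the stress cytokine Gdf15, also a leading gene of cluster 5, had 22.4 and 63.7 and the pro-apoptotic Bbc3 39.4 and 72.3. Pro-apoptotic and death signalling genes (−0.02, 4 of 23 lower, 2 higher, percentile 27.2) included the necroptosis genes Ripk3 at 20.2 and 5.33 and Mlkl at 4.92 and 0.976. Pro-survival BCL2 and IAP family genes had a median of 0.17 (0 of 9 lower or higher, percentile 89.4).

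Genes that work with BAP1 mostly differed by less than 1.5-fold. Its partner proteins had a median of 0.21 (0 of 10 lower, 1 higher, percentile 97.4) and the Polycomb subunits, of complexes that place ubiquitin on H2A or methylate histone H3, 0.12 (2 of 27 lower, 1 higher, percentile 93.2). Hox genes had a median of −0.03 (3 of 29 lower, 2 higher, percentile 46.4), with Hoxc4 at 22.4 and 7.40 CPM and Hoxc8 at 16.4 and 8.13. The IP3 receptors had a median of −0.01 (3 measured, percentile 54.4).

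Unfolded protein and amino acid stress genes (0.16, 3 of 18 lower, 3 higher, percentile 94.4) included the transcription factor Ddit3 at 65.1 and 109 CPM and the pseudokinase Trib3 at 22.0 and 39.8. Hypoxia genes (0.03, 1 of 12 lower, 1 higher, percentile 69.2) included the angiogenic factor Vegfa at 3.26 and 9.42 and the mitophagy receptor Bnip3 at 7.44 and 1.87. Oxidative stress and ferroptosis genes (0.07, 1 of 17 lower, 2 higher, percentile 62.4) included the quinone reductase Nqo1 at 13.5 and 38.4. Glycolysis genes (−0.0028, 3 of 16 lower, 0 higher, percentile 45.4) included the lactate transporter Slc16a3 at 6.35 and 1.20. CDK inhibitors had a median of 0.08 (2 of 7 lower, 1 higher, percentile 72.2) and heat shock genes −0.01 (0 of 12 lower or higher, percentile 24.1). Desmosome and adherens junction genes had a median of −0.02 (0 of 12 lower or higher, percentile 19.0) and ribosomal proteins 0.03 (0 of 85 lower or higher, percentile 19.6). Nuclear oxidative phosphorylation genes had a median of −0.01 (1 of 86 lower, 1 higher, percentile 4.55) and mitochondrially encoded genes −0.22 (3 of 13 lower, 0 higher, percentile 3.47).

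Genes of pigment cells, neural crest cells and antigen-presenting cells were also within the range of their random lists in clusters 0 to 5. Pigmentation genes had a median of −0.14 (4 of 23 lower, 1 higher, percentile 16.1), and the melanosome gene Pmel had 72.6 and 65.7 CPM. In melanocyte-like cells Pmel had 9591 and 8097 CPM, past the limit of 10 times used here for free RNA. Pigment RNA in clusters 0 to 5 may therefore be free RNA, which was not tested. Neural crest and dedifferentiated melanocyte genes had a median of −0.25 (3 of 10 lower, 1 higher, percentile 14.2) and MHC class II genes −0.78 (4 of 5 lower, 0 higher, percentile 5.96). Keratin RNA was seen in the other classes too, as Krt14 had 5742 and 4622 CPM in clusters 0 to 5 and still 366 and 303 in myeloid-like cells and 399 and 316 in Schwann-like cells.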

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

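The comparisons in this part were chosen after the values were seen, and the differences between cell classes were not tested, since each class has 1 library per genotype. Spp1, the osteopontin gene, had a log2 ratio of −2.04 (−2.34 to −1.75) in melanocyte-like cells and 0.88 in clusters 0 to 5, opposite directions under the same comparison. Ly6a, a surface antigen of stem cells and activated lymphocytes, had 472 and 19 UMIs in the 36 and 20 myeloid-like cells, a log2 ratio of −3.50, while in clusters 0 to 5 it was higher in the library labelled knockout, with 495 and 804 CPM. Ppbp, a platelet chemokine gene, had a log2 ratio of 4.13 in myeloid-like cells against −1.33 in clusters 0 to 5, and 1 cell held 916 of its 927 myeloid-like UMIs in the library labelled knockout.

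The cells of cluster 6, whose genes were not compared between the libraries by class, held single cells with RNA that no other cell of their library had at over 100 UMIs. A cell of the library labelled knockout had 2587 UMIs of Obp2a among 12269, and 289 further UMIs lay in 250 of the other cells. A cell of the library labelled wild type with 40185 UMIs had 616 of Tnni1, a troponin of slow skeletal muscle, with 86 further UMIs in 79 of the other cells.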

How the results depend on the processing

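No paired analysis was possible because each genotype has 1 library and the labels give no replicate numbers. Every alternative fixed beforehand was run. The common UMI minimum, the top cell left out, equal clusters, clusters 3 and 4 left out and thinning to 8000 were added after seeing the data. Of 70 alternative values of class shares 57 stayed within the counting interval and 13 moved. The melanocyte-like share of the library labelled knockout was 3.20% with the stricter cell filter and 1.67% at the common minimum, where clusters 0 to 5 held 94.1%. Assigning each cell by its mean marker level gave 2.88% and 5.35% melanocyte-like, 8.68% and 5.01% Schwann-like and 3.87% and 2.82% myeloid-like. The remaining 84.6% and 86.8% were cells led by any other marker set, counted in place of clusters 0 to 5. Genes at least 2-fold higher and lower numbered 58 and 156 after thinning and 153 and 528 with at least 300 UMIs, where fewer genes were compared, and 524 and 1527 with at least 20 UMIs, where more were. Of 442 alternative list medians 430 stayed within their interval, 11 moved and 1 changed sign. The S phase median was −0.10 after thinning, −0.23 with equal clusters and 0.047 without cluster 3, and the G2 and M phase median −0.025 with equal clusters and −0.67 without cluster 3, the cluster these genes set apart. Ube2c was seen in 6.07% of cells labelled wild type at 1000 UMIs, 11.6% at 4000 and 15.5% at 8000, and in 3.17% and 5.70% of cells labelled knockout at 4000 and 8000, as a larger sample of UMIs gives. Of 360 alternative log2 ratios of the 24 named genes 323 stayed within their interval, 37 moved and 0 changed sign. Thinning leaves few UMIs of such genes and gave a log2 ratio of Nrn1 of −0.27, a log2 ratio of F2rl2 of 1.73 and a log2 ratio of Lce3a of −3.97. Where no reason is given, the cause was not tested. The small classes held only 20 to 72 cells each per library, which limits what their values can show.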

Other observations

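The pigment level that splits the melanocyte-like cells, the comparisons within them, and the tests of Ube2c at equal depth, of G2 and M phase genes outside cluster 3 and of free Esr1 RNA were chosen only after the result was seen. Pigment cells over that level, 20 in the library labelled wild type and 53 in the library labelled knockout, are too few for the ranking of genes, so single genes are given as values. Their pigment RNA is partly set by that choice, as Dct and Pmel enter it. Dct, a melanin synthesis enzyme, had 21748 and 19394 CPM, the melanosome gene Pmel 17351 and 16044 and tyrosinase, Tyr, 870.1 and 814, and the pigmentation list had a median log2 ratio of −0.02. Kcnj13, an inward rectifier potassium channel, was 11.7-fold higher in the library labelled knockout, from 123 to 1437 CPM, with UMIs in 5 of 20 and 40 of 53 cells. In clusters 0 to 5 it had 1.82 and 8.36 CPM. Cited1, a transcriptional coactivator, had 649 and 1788 CPM and Oca2, a melanosomal channel, 327 and 623. Serpine2, a protease inhibitor, had 390.5 and 112, and Id3, an inhibitor of differentiation factors, 352 and 133. G2 and M phase genes had a median of −1.59 (20 of 27 lower, 0 higher), against −0.32 (13 of 37 lower, 4 higher) over the whole melanocyte-like cluster. The first value rests on few cells, with UMIs of Cdk1 in 9 of 20 and 16 of 53 cells and of Ube2c in 6 and 4.

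A second group of values comes from the myeloid-like cells. C1qb, a complement gene of macrophages, had 2213 and 816 CPM, while Lyz2, the lysozyme gene, had 2638 and 6156, from 36 and 20 cells. In the library labelled knockout 1 cell held 54.6% of the C1qb UMIs and 1 cell 43.0% of the Lyz2 UMIs. Several of the largest ratios in the melanocyte-like cluster came mostly from cells under the pigment level. Those cells still had a median of 13212 and 5105.5 CPM from the 4 pigment genes. Ly6a had 14 and 1425 UMIs in the cluster, with 1398 of the latter in cells under the pigment level and 648 in 1 cell.

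The melanocyte-like share was higher in the library labelled knockout, whose deposited cells start at a lower UMI count. That lower minimum may account for the difference, as with 1 common minimum and new clusters the ratio of shares was 1.60 (0.870 to 3.00), which leaves this open because the cells are few. A difference due to the genotype stays among the open explanations and was not tested.

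Lower G2 and M phase genes in clusters 0 to 5 could come from depth or from another makeup of the clusters. Depth is argued against by Ube2c at 8000 UMIs per cell, where the ratio of shares was 0.367 (0.286 to 0.468). With the 6 clusters weighted equally the median was −0.025 (−0.16 to 0.12), the value that makeup alone would give, but that mean is led by cluster 3, which these same genes set apart. With the other 5 clusters weighted equally it was −0.69 (−1.03 to −0.21), below the median inside each of them. The medians inside clusters 1, 2 and 5 were −0.67, −0.50 and −0.35, so differences between whole clusters do not give all of it. A cluster can still mix cycling and other cells, so the test cannot exclude another makeup within clusters. Slower cycling due to the genotype is an untested hypothesis, and inside cluster 0, at −0.10 (−0.44 to 0.17), and cluster 4, at −0.12 (−0.55 to 0.17), no difference was detectable.

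Esr1 was higher in the library labelled knockout in each cell class, and both genotypes carry CreERT2, a fusion with part of the human estrogen receptor. Free RNA from 1 cell type is argued against, since the highest cluster had 1.46 times (0.969 to 2.11) the Esr1 level of clusters 0 to 5 in that library, and no upper bound of a cluster there passed 2.37 times. A candidate explanation is that transgene RNA is counted as Esr1, with less of it in the library labelled wild type. In that case RNA of the interrupted locus, Gt(ROSA)26Sor, would be lower in the library labelled knockout, and its log2 ratio was −0.44 (−0.51 to −0.36). This is weak evidence, as 11.2% of 9133 genes with at least 1000 UMIs lay at or below that ratio, and a response of Esr1 itself to the genotype stays open and untested.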
